A study of Mus musculus with 4 samples.

How the data were processed

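ATAC-seq libraries were made from 50000 bone marrow-derived macrophages each, per the labels' protocols, after 5 days of culture with 10% M-CSF. The 4 libraries were WT untreated, WT IL-4, Slc6a8 KO untreated and Slc6a8 KO IL-4, with IL-4 at 10 ng/mL for 6 h and 1 library per group. The deposited data used here are 4 peak lists, 1 per library, with a position and a score for each peak.

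Bowtie2 2.2.5, MACS 1.4.2, HOMER and the build mm10 are named per the submitters' processing notes, which give no parameters, roles or order, and no HOMER version. The score of each peak is the authors' value as deposited. It ran from 50.01 to 3100 in the WT untreated list, the pattern of -10 times the log10 p that MACS 1.4 writes, but no header states its unit. It was used only to describe, rank or filter peaks within a list. Read depth is not given in the sources used here, so the precision of a peak's presence or absence is unknown. Peak width, number and score all move with depth.

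Lists were compared by overlap of at least 1 bp. A peak of the first library with no overlap in the second was counted as gained, the reverse as lost, and the log2 ratio of the 2 counts was taken. The shared percent is the share of merged regions of 2 lists with a peak of both. Intervals are exact Clopper-Pearson 95% intervals for counting error. No p-value was computed, because no group had a second library. The comparisons were IL-4 against untreated in each genotype and KO against WT under each treatment.

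Genes were the 21883 protein-coding genes of a table of assembly GRCm38.p6, which has the coordinates of mm10. The table holds gene spans without strand, exons or sequence. The planned distance to the transcription start site was therefore replaced by the distance to either end of the span, 1 kb counting as a gene edge, and exons were not separated from introns. A locus was the span extended by 10 kb on each side. The planned comparison of 15 sequence motifs was not run, because no genome sequence was used here. The planned count of independent lists for gained regions was replaced by one over gene loci, because every merged region without an untreated peak holds an IL-4 peak by construction. Peaks were moved by 20 kb to check the annotation.

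The 23 gene lists held 465 entries. Of these 461 were matched by symbol, 1 by an older symbol (Ear11, now Rnase2a), 1 repeated another entry (Emr1, now Adgre1) and 2 (Cxcl11 and Mx1) were not matched to a protein-coding gene. The lists cover the IL-4 response, IL-4 receptor and STAT6 signalling, interferon response, NF-kB, creatine and arginine metabolism, SWI/SNF subunits, macrophage identity, AP-1, MHC class II, oxidative phosphorylation, glycolysis, lipids, lysosome, cell cycle, housekeeping genes, and markers of neutrophils, T cells, B cells, dendritic cells, mast cells, erythroid cells, fibroblasts, and neurons and hepatocytes. For each list, the log2 ratio of locus peaks (with 0.5 added to each count) was taken minus that of all genes. Its percentile was found among 10000 random lists of the same size, matched on the number of locus peaks, with random seed 11.

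Genes named in the text follow a rule. Slc6a8, Arg1, Retnla, Chil3, Mrc1, Nos2, Stat6, Irf1 and Il4ra are always named. For each comparison, up to 10 gained and 10 lost list genes with the highest-scoring library-specific peak at their locus are named, and the genes with an end within 10 kb of the 5 highest such peaks in each direction. Some genes that the rule names are not reported here. Genes named for an edge peak within a list are examples chosen after the values were seen.

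The alternatives were reciprocal overlap of 50%, a score of 100 or more, the 9930 highest-scoring peaks of each list, autosomes only, no peak within 500 bp, edges of 2.5 kb and loci extended by 50 kb. Added after the data were seen were a score of 100 or more in one list with no peak at any score in the other, the 10 score strata, the gene-locus background, the counts over 6 pairs and the difference of the list values between genotypes.

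Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The overlap code was tested on simulated data made from the 17339 WT untreated peaks, where 3000 of 3000 planted losses and 700 of 700 planted gains were found. In the list code, run on 21883 genes, a planted list of 30 genes reached percentile 100, and 1 of 40 unchanged lists lay outside the central 95%.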

Results

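Open chromatin was mapped by ATAC-seq, in which the transposase Tn5 inserts adapters into accessible DNA, in macrophages grown from the bone marrow of C57BL/6 mice. The macrophages came from wild-type mice (WT) or from mice without Slc6a8 (KO), the X-linked gene of the creatine transporter. They were left untreated or received IL-4, the cytokine of alternative activation, at 10 ng/mL for 6 h. The study asked how accessibility differs in polarizing macrophages that lack creatine. Each of the 4 groups held 1 library. No difference could therefore be set against replicate error, and every comparison is between these libraries, not between the conditions. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. The read depth is unknown.

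The targeted gene offered no check of the labels, because no library had a peak at Slc6a8 (chromosome X, 73673133 to 73682502, mm10) or within 10 kb of it. Peaks on chromosome X numbered 336 in WT untreated, 164 in WT IL-4, 283 in KO untreated and 185 in KO IL-4. Those on chromosome Y numbered 18, 14, 15 and 15 in the same order.

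The untreated libraries held more peaks than the IL-4 libraries in both genotypes. WT untreated had 17339 peaks covering 8.39 Mb and WT IL-4 had 9930 covering 6.22 Mb. KO untreated had 13714 peaks covering 7.88 Mb and KO IL-4 had 10443 covering 5.80 Mb. The median peak width was 438 bp, 587 bp, 530 bp and 514 bp in that order. The median score, the authors' value for each peak, was 101.1, 85.5, 94.3 and 86.1 in that order, and it ranks peaks only within a library. Of the 20540 regions formed by merging the 4 lists, 6672 had a peak in all 4 libraries. Among the 30 regions with a score of 1000 or more in any library, 29 had a peak in all 4.

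Regions found in all 4 libraries lay at gene edges more often than regions found in exactly 2 libraries or in WT untreated alone. A gene edge is here either end of a protein-coding gene's span, within 1 kb. The edge share was 42.8% of peaks (42.0 to 43.5) in WT untreated, 52.0% (51.1 to 53.0) in WT IL-4, 47.8% (47.0 to 48.7) in KO untreated and 51.4% (50.5 to 52.4) in KO IL-4. It was 61.8% (60.6 to 63.0) of the regions found in all 4 libraries and 6.51% (6.14 to 6.88) after WT untreated peaks were moved by 20 kb. Of the regions in WT untreated alone it was 21.2% (19.9 to 22.5), and of those in exactly 2 libraries 16.5% to 32.9%. Overlap between libraries rose with score, so sharing and score were not told apart here. With the highest-scoring 9930 peaks of each list, the order turned: 54.5% (53.5 to 55.5) in WT untreated against 52.0% in WT IL-4, and 55.3% (54.3 to 56.3) in KO untreated against 52.6% (51.6 to 53.6) in KO IL-4.

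In WT macrophages, peaks absent from the untreated library appeared with IL-4 at Ptgs1, which encodes cyclooxygenase 1, and at Kdm6b, a histone H3 lysine 27 demethylase. The Ptgs1 peak lay at the gene's edge (chromosome 2, 36216547 to 36217403, score 91.0) and the Kdm6b peak inside the gene span (chromosome 11, 69410145 to 69411003, score 84.4). Far more peaks were found in the untreated library without a counterpart after IL-4. Among them were peaks at Tgm2 (transglutaminase 2, score 204), Fasn (fatty acid synthase, 193), Nfkbiz (an atypical inhibitor of NF-kB, 191) and Lgmn (a lysosomal protease, 256). A peak of the first library with no overlap in the second is called gained, and the reverse lost. By that count 1024 peaks were gained and 8273 lost with IL-4, a log2 ratio of gained over lost of -3.01 (-3.11 to -2.92). Both libraries had a peak in 48.9% (48.1 to 49.6) of the 18177 merged regions.

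The other fixed-list genes with the highest-scoring gained peaks in WT were Itgae (an integrin subunit, score 87.0), Atp6v1a (72.9), H2-DMa, H2-DMb1 and H2-DMb2 (1 peak of 68.0 shared by these neighbouring MHC class II loci), Afp (62.1), Jak1 (61.7) and Tyrobp (61.7). The remaining genes with the highest-scoring lost peaks were Eef2 (179), Laptm5 (169), Ndufs1 (166), Cox5b (163), Slc17a7 (163) and Irf2 (156). The score of 91.0 at Ptgs1 was at percentile 54.7 of the WT IL-4 list, while 256 at Lgmn was at percentile 88.3 of the WT untreated list. The gained peak with the highest score of all (168, chromosome 10, 25128267 to 25129035) lay 40439 bp from Akap7, the nearest gene. Of the 5 highest gained peaks, 1 lay within 10 kb of a gene end, at Eppk1 (137). Of the 5 highest lost peaks, 3 did, at Wdr20 (310), Ccno (281) and Zdhhc12 (274).

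The always-named macrophage genes gave few peaks in WT. Retnla, Chil3 and Nos2 had no locus peak, where a locus is the gene span extended by 10 kb on each side. Mrc1, the mannose receptor gene, had 2 in untreated and 0 in IL-4. Il4ra, the IL-4 receptor alpha gene, had 3 and 0. Stat6, which encodes the transcription factor activated by IL-4, had 3 and 2, with the edge peak (score 92.2) lost. Irf1 had 2 in both. At Arg1, the arginase gene, the peak at 24930058 to 24930590 on chromosome 10 scored 121 in WT IL-4, and a peak of 64.9 overlapped it in WT untreated. A second Arg1 peak, at 24911218 to 24911767 with a score of 120, was lost.

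The gene lists and the 4 comparisons were fixed before the data were examined. The lists lost locus peaks with IL-4 in WT about as all genes did. Over all protein-coding genes the log2 ratio of locus peaks was -0.75, and list values are given relative to it, with a percentile among 10000 random lists matched on the number of peaks. The 35 genes of the IL-4 response list went from 36 to 20 peaks (-0.08, percentile 41.6) and the interferon list of 33 genes from 36 to 17 (-0.31, percentile 11.03). At gene edges a gene counts as gained or lost by whether any peak reaches within 1 kb of its ends, so a peak that only changes width can alter the count. There, 19 interferon genes had a peak untreated and 10 with IL-4: 9 were lost, including Cxcl10, Ifit2, Ifit3 and Irf8, and 0 gained. At equal list lengths 11 and 10 had one, with 3 lost, Ifit2 among them but not Cxcl10, Ifit3 or Irf8, and 2 gained, and the locus value turned to 0.10 (percentile 72.8). Of the macrophage identity list (29 genes) 17 had an edge peak untreated and 8 with IL-4. The 10 lost included Spi1 and Cebpb, which encode lineage transcription factors, Cx3cr1 and Trem2, and the 1 gained was Tyrobp. Equal list lengths gave 10 and 8: 5 were lost, Cebpb, Cx3cr1 and Trem2 among them but not Spi1, and Adgre1, Lyz2 and Tyrobp were gained. Equal lengths leave out WT untreated peaks with scores below 89.57 and KO untreated peaks below 67.78. A gene can then count as gained because its untreated peak was left out. Adgre1, Lyz2 and the 2 interferon genes gained at equal lengths were such cases, with an edge peak in the full WT untreated list. Of the 26 housekeeping genes, 21 had an edge peak untreated and 14 with IL-4, Eef2 and Polr2a among the lost, at equal list lengths too. Over all 21883 genes the count went from 8355 to 6202.

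Lost peaks in WT were mostly peaks of low score. In the lowest score quartile of the WT untreated list 18.2% (17.1 to 19.4) had an overlapping peak in WT IL-4, and in the highest quartile 95.4% (94.7 to 96.0). With the 9930 highest-scoring peaks of each list the log2 ratio was 0.01, a balance that lists of equal length force, and the shared share was 58.7%.

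**Figure D1:**
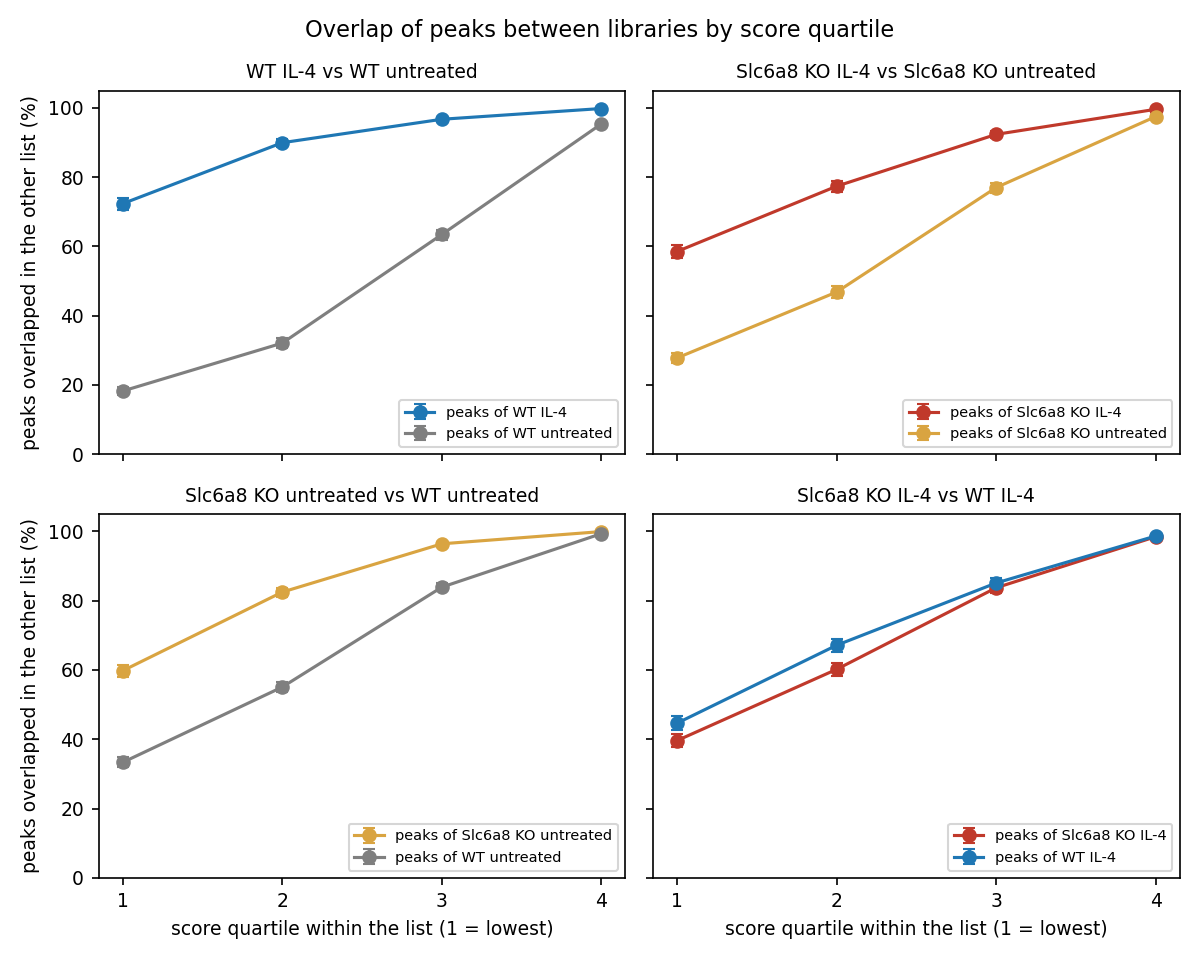
Percent of each library's peaks that overlap a peak of the other library (vertical axis) by score quartile within its own list (horizontal axis, 1 is the lowest), for the 4 comparisons; points are percentages and bars exact 95% intervals for counting error. Overlap climbs with score in every list, from 18.2% to 95.4% for WT untreated peaks in WT IL-4.

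In KO macrophages IL-4 again came with a gained peak at the edge of Ptgs1 (score 93.8), overlapping the WT one, and with gained peaks at Egr2 (a zinc-finger transcription factor, 80.4) and at the edge of Ccl24 (an eotaxin chemokine, 78.6). WT untreated already had overlapping peaks at Egr2 (70.6) and Ccl24 (97.1), and the Ccl24 peak was lost with IL-4 in WT. Lost peaks lay at Irs2, an adaptor of the IL-4 receptor (score 170 at the gene edge), at Plin2 (a lipid droplet protein, 141) and at Abca1 (a cholesterol exporter, 121). Another (139, chromosome 10, 80248969 to 80249609) lay outside the span of Gamt, the methyltransferase gene of creatine synthesis, but within 10 kb of it. The edge of Gamt itself had a peak in both KO libraries. In all 1885 peaks were gained and 5174 lost, a log2 ratio of -1.46 (-1.53 to -1.38). Both libraries had a peak in 54.6% (53.8 to 55.4) of the 15557 merged regions.

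Further KO genes with the highest gained scores were Irf2 (99.8), Fos (84.7), Ywhaz (81.8), Actb (80.3), Lamp2 (79.8) and Mcm7 (76.5). Of these, the peaks at Irf2, Fos and Lamp2 overlapped peaks of both WT libraries, so only KO untreated lacked them. The Actb peak overlapped one of WT untreated (51.4). Those with the highest lost scores were Ndufb3 (139), Aldoa (138), Xcr1 (129), Maf (126), Tbp (122) and Nr1h2 (122). The highest gained peaks within 10 kb of a gene end were at Alg1 (197), Msx3 (163) and Casp6 (148), and the highest lost ones at Arhgap17 (282), 9430078G10Rik (243), Stab1 (242), Churc1 (236) and Mbnl1 (227). Mrc1 went from 2 locus peaks to 0, Il4ra from 1 to 0 and Arg1 from 2 to 0. Stat6 had 3 in both KO libraries, Irf1 had 2 in both, and Retnla, Chil3 and Nos2 had none.

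The IL-4 response list held 26 locus peaks in KO untreated and 28 in KO IL-4, while over all genes the log2 ratio was -0.38. Relative to all genes the list stood at 0.49, percentile 99.3. At its gene edges 5 genes had a peak untreated and 8 with IL-4: Ccl24, Clec10a, Ptgs1 and Tgm2 were gained and Kdm6b lost, with Myc in place of Tgm2 at equal list lengths. Myc had an edge peak in the full KO untreated list, which the equal-length cut left out. At Kdm6b an overlapping peak remained and only its reach towards the gene end differed. The MHC class II list of 15 genes went from 8 to 10 (0.69, percentile 98.8), including 1 gained peak that lies within the loci of both H2-Aa and H2-Eb1; each peak counts once per list. Its value was 1.098 at equal list lengths (percentile 99.8) and with a score of 100 or more 0.60 (percentile 90.3). The edge count of this list did not rise: 4 genes had an edge peak untreated and 3 with IL-4, and at equal list lengths 2 in each. The AP-1 and immediate early list of 17 genes went from 30 to 17 (-0.42, percentile 1.24, or 38.9 with a score of 100 or more). The edge peaks of Dusp1 and Ier2 were lost and that of Fos gained, of which only the gain at Fos held at equal list lengths. Both WT libraries had a peak that overlapped the gained Fos peak. The interferon list went from 32 to 22 (-0.15, percentile 36.1), and its direction turned with lists of equal length (0.38, percentile 96.7). With peaks of score 100 or more the IL-4 response value was -0.62 (percentile 23.3), from 10 peaks untreated and 4 with IL-4. At equal list lengths it was 0.76 (percentile 99.9) and the log2 ratio of gained over lost was -0.01.

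**Figure D2:**
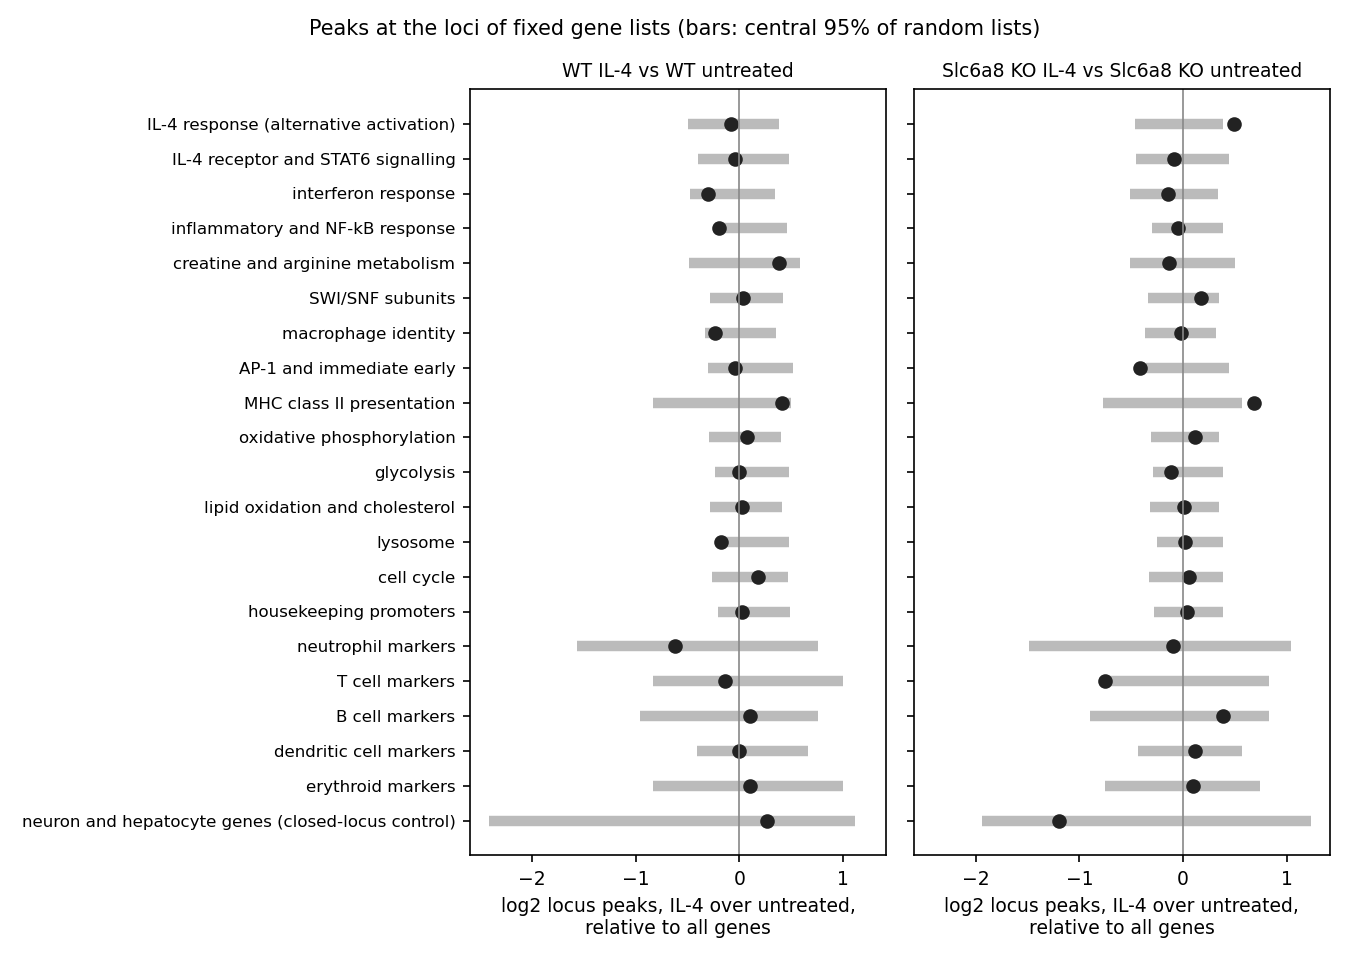
Log2 ratio of locus peaks, IL-4 over untreated, minus that of all genes (horizontal axis) for 21 fixed gene lists (listed vertically) in WT (left) and KO (right); dots are the lists and bars the central 95% of 10000 random lists matched on peak number. In KO the dots of the IL-4 response list (0.49) and the MHC class II list (0.69) lie above their bars and that of the AP-1 list (-0.42) below; the mast cell and fibroblast lists, with at most 1 peak, are not drawn.

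Regions gained in both genotypes included those of Ptgs1, Kdm6b and Itgae named above. Of the 1009 merged regions gained in WT and 1864 gained in KO, 127 were gained in both, and 21.5% of the WT ones had a peak in KO IL-4 against 29.4% with a peak in KO untreated. The highest of the 127, ranked after the values were seen by the lower of the 2 scores, lay 213503 bp from Tet2 (chromosome 3, 133758273 to 133759007, lower score 125) and 40439 bp from Akap7 (109). The next lay inside Rab3il1 (96.8) and 21873 bp from Gatm, which encodes the first enzyme of creatine synthesis (91.0). Only 16.5% (10.5 to 24.2) of the 127 lay at a gene edge. Over gene loci, a background chosen after the data were seen, 9099 had no peak in either untreated library. Of these, 131 had a peak in WT IL-4, 145 in KO IL-4 and 21 in both, where independent lists give 2.09. That number takes every locus as equally likely to hold a peak. Loci differ in length and neighbouring loci can share a peak, so an excess over it does not by itself show a shared response. Of the 11539 regions with a peak in both untreated libraries, 3632 were lost in WT, 3380 in KO and 2145 in both. Independent losses give 1064, and 1755 when independence is taken within 10 strata of the WT untreated score, an addition also made after the data were seen.

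Regions found in exactly 2 libraries were counted for all 6 pairs, an addition made after the data were seen. The 2 treatment pairs together had 2272, against 799 for the genotype pairs and 832 for the mixed pairs. With a score of 100 or more these sums were 1458, 258 and 266, and with lists of equal length 1020, 722 and 767. With all peaks, 2145 regions had a peak in the untreated libraries only, the most of any pair, and 127 in the IL-4 libraries only, the fewest. The WT pair had 550, the KO pair 249, and the mixed pairs, which share neither treatment nor genotype, 625 and 207. At equal list lengths the untreated pair had 566, the IL-4 pair 454, the WT pair 349, the KO pair 373 and the mixed pairs 382 and 385. At equal lengths 33.6% of the regions gained in WT had a peak in KO IL-4 and 31.0% in KO untreated. The highest regions of the genotype pairs, again ranked after the values were seen, lay at Cgas (edge, lower score 125), Sirpa (115) and Foxo1 (edge, 106) for WT and at Slc16a7 (edge, 132) for KO.

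**Figure D3:**
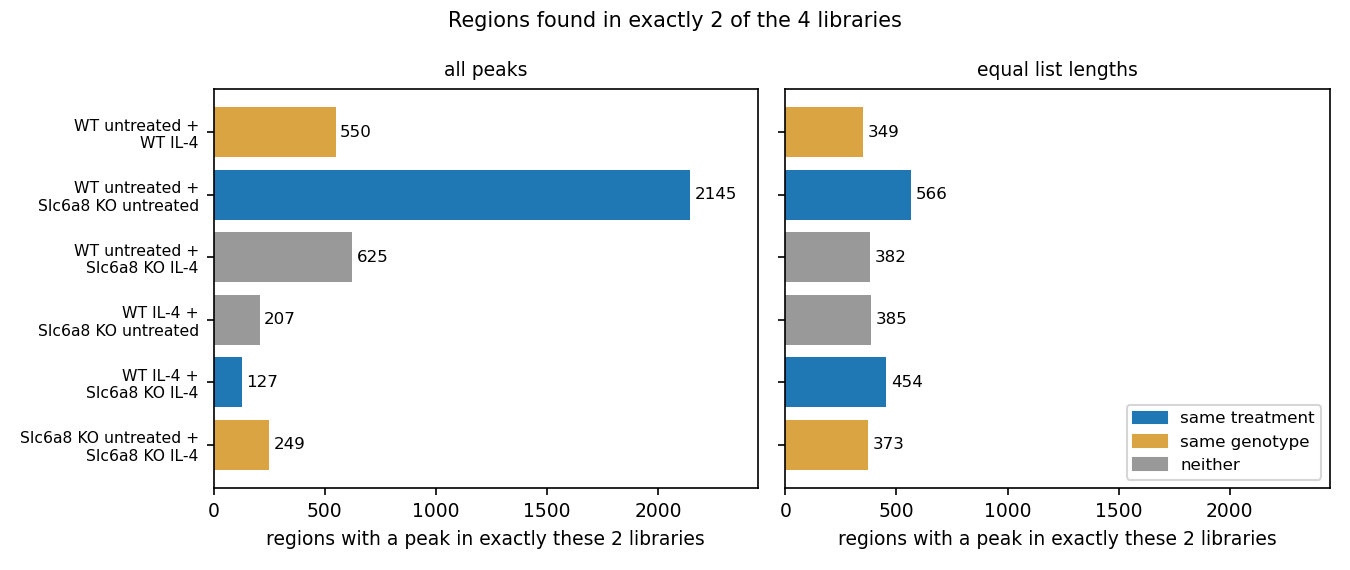
Number of merged regions with a peak in exactly 2 of the 4 libraries (horizontal axis) for each of the 6 pairs (listed vertically), with all peaks (left) and with the 9930 highest-scoring peaks of each list (right); colours mark pairs of the same treatment, the same genotype or neither. At equal list lengths the untreated pair has 566 and the IL-4 pair 454, and the other pairs 349 to 385.

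In untreated macrophages, peaks at some macrophage genes were found in WT and not in KO, and others in KO and not in WT. The edge peak of Cebpb (chromosome 2, 167688489 to 167689291, score 151), the locus peaks of Icam1 (an adhesion molecule, highest score 182) and that at the edge of Spi1 (53.2) were absent from KO untreated. KO had a gained peak inside Spi1 (88.7), at the edge of Abca1 (121) and at Egr3 (104.5). In all 2106 peaks were gained and 5565 lost in KO against WT, a log2 ratio of -1.40 (-1.48 to -1.33). Both libraries had a peak in 60.1% (59.4 to 60.8) of 19226 regions, the highest share of the 4 comparisons.

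The macrophage identity list held 56 locus peaks in WT untreated and 36 in KO untreated (-0.33, percentile 0.66 against -0.30 over all genes). Its edge peaks numbered 17 and 14: 7 were lost, among them Cebpb, Spi1, C1qa and Fcgr1, and 4 gained, Cd68, Itgam, Laptm5 and Runx1. The locus value at equal list lengths was -0.07 (percentile 28.9) and the edge counts turned to 10 and 11, with C1qa and Cebpb lost and Laptm5, Lyz2 and Mertk gained. Lyz2 and Mertk had an edge peak in the full WT untreated list, which the equal-length cut left out. At Laptm5 a WT untreated peak (169) overlapped the KO one (102), and only its reach towards the gene end differed. With edges of 2.5 kb 7 genes were again lost, but not Spi1. The 4 then gained were Aif1, Apoe, Csf1r and Itgam, of which only Itgam was also gained with edges of 1 kb. The inflammatory and NF-kB list had 5 edge peaks lost, Icam1 and Nfkbiz among them, and 4 gained, Il12b, Il23a, Nfkb1 and Tlr2, and its locus value was -0.10 (percentile 13.4); at equal list lengths 2 were lost, Cd80 and Rela, and 1 gained, Nfkb1. The cell cycle list of 25 genes held 33 and 34 (0.34, percentile 98.0; 87.6 at equal list lengths), with 1 edge peak gained, at Bub1, and none at equal list lengths. Other genes with the highest lost scores were Irf2 (156), Plin2 (136), Socs3 (127), Csf3r (125), Cd63 (124.5), Ldha (124) and Fos (124). Those with the highest gained scores were Aldoa (138), Rab7 (95.1), Srebf1 (87.0), Arid1b (85.0), Jak1 (84.1), Myc (81.1) and Rsad2 (80.2). The highest gained peaks within 10 kb of a gene end were at Ctso (163), Glrx2 (158.5), Rpl39 (147) and Rps6kc1 (146), and the highest lost ones at Bloc1s5 (245) and Map3k8 (231), a kinase of inflammatory signalling. The 4 Arg1 peaks of the untreated libraries overlapped in pairs, with scores of 120 and 67.2 at 1 region and 64.9 and 59.8 at the other. In the highest score quartile of WT untreated 99.4% of peaks (99.1 to 99.6) had an overlapping KO peak, and with lists of equal length the log2 ratio was 0.02.

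After IL-4, the KO library had peaks that WT lacked near Myc (score 161), at the edges of Fasn (140) and Fosl2 (an AP-1 subunit, 135), and at Hk2 (hexokinase 2, 126). WT had peaks that KO lacked at Tnf (121, inside the gene), Arg1 (121), Mmp8 (neutrophil collagenase, 134) and the edge of Nr1h2 (liver X receptor beta, 119). The numbers were close: 3082 peaks of KO IL-4 had no overlap in WT IL-4 and 2594 the reverse, a log2 ratio of 0.25 (0.17 to 0.32). Both had a peak in 56.3% (55.5 to 57.2) of 12993 regions. With lists of equal length the ratio was -0.01.

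KO-only and WT-only here mean a peak in the named IL-4 library and none in the other, whatever the untreated libraries held. Other genes with KO-only peaks were Cpt1a (114), Ndufs1 (112), Atp6v1h (106) and Ier3 (102). Those with WT-only peaks were Srebf1 (107), Fosb (107), Ndufb3 (107), Tbp (102), Arid2 (99.6) and Acadl (97.3). The KO-only peaks at Fasn, Fosl2, Hk2, Cpt1a, Atp6v1h and Ier3 overlapped peaks of both untreated libraries. So did the WT-only peaks at Arg1, Fosb, Arid2 and Acadl. The highest KO-only peaks were at Gm15246 (227), Srsf2 (213), Zfp141 (186), Wdr5b (184) and Srrm1 (181), all at gene edges. The highest WT-only peaks were at Frmd6 (157), Chchd2 (155), Zc3h8 (154), C2cd2 (153) and Cdk11b (152). The IL-4 response list held 20 locus peaks in WT IL-4 and 28 in KO IL-4 (0.41, percentile 96.6), a direction that turned with a score of 100 or more (-0.11); Ccl24, Clec10a, Myc and Tgm2 had an edge peak in KO IL-4 and not in WT IL-4, all but Tgm2 at equal list lengths too. The interferon list held 17 and 22 (0.29, percentile 91.6), with edge peaks in KO and not in WT at genes including Gbp3, Ifit2, Ifit3 and Irgm1, and the reverse at Irf9. Stat6 had an edge peak in KO IL-4 (59.3) and not in WT IL-4. The creatine and arginine list of 16 genes held 13 and 11 (-0.30, percentile 14.4). Ckb, Ckm and Slc7a1 had an edge peak in WT IL-4 and not in KO IL-4.

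**Figure D4:**
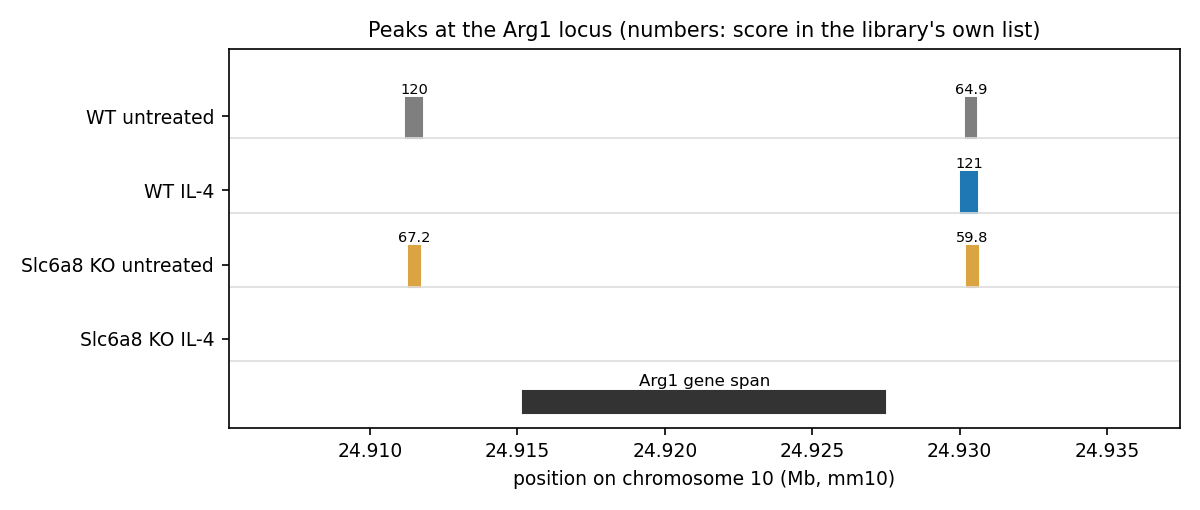
Peaks of the 4 libraries (stacked) on chromosome 10 around Arg1 (horizontal axis, position in Mb, mm10); boxes span each peak, numbers are its score in that library's own list and the dark box is the gene span. The region near 24930058 has a peak in WT untreated (64.9), WT IL-4 (121) and KO untreated (59.8) and none in KO IL-4.

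The other pathway lists are given as locus peaks in WT untreated, WT IL-4, KO untreated and KO IL-4, and all their values lay within the central 95% of random lists. IL-4 receptor and STAT6 signalling, 16 genes, held 35, 20, 28 and 20. The edge peaks of Irs2 and Jak3 were lost with IL-4 in both genotypes, but at equal list lengths only the loss of Irs2 in KO was found. The inflammatory and NF-kB list, 31 genes, held 45, 23, 34 and 25. At Tnf the peak of WT IL-4 (121) overlapped one of WT untreated (87.7), and both KO libraries had none. SWI/SNF chromatin remodelling subunits, 22 genes, held 43, 26, 37 and 32, and Bcl7c and Brd7 lost their edge peak in both genotypes, at equal list lengths Brd7 alone. Oxidative phosphorylation, 31 genes, held 50, 31, 40 and 33, and glycolysis, 22 genes, held 41, 24, 37 and 26. Lipid oxidation and cholesterol, 28 genes, held 50, 30, 39 and 30, with edge peaks of Hadha and Hadhb lost in both genotypes, and in KO alone at equal list lengths. The lysosome list, 25 genes, held 54, 28, 44 and 34, and the housekeeping list 45, 27, 37 and 29. The creatine and arginine list held 17 and 13 in WT and 16 and 11 in KO; Ckb gained an edge peak with IL-4 in WT and lost it in KO, a loss not found at equal list lengths.

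Lists of other cell types are given in the same order, and apart from the dendritic cell list they had few locus peaks. Dendritic cell markers, 10 genes, held 19, 11, 17 and 14, mostly at Tcf4, Zbtb46, Xcr1 and Itgae, some of which other immune cells also express. Neutrophil markers, 14 genes, held 6, 2, 3 and 2, T cell markers, 12 genes, 6, 3, 5 and 2, and B cell markers, 10 genes, 5, 3, 3 and 3. Erythroid markers, 11 genes, held 5, 3, 5 and 4, mast cell and basophil markers 0 in each, fibroblast and stromal markers 1, 0, 0 and 0, and neuron and hepatocyte genes 3, 2, 4 and 1. None of these values lay outside the central 95% of random lists, and these lists are small. Over all 23 lists and 4 comparisons, 5 of 92 values lay outside that range, where 4.6 are expected by counting alone. With loci extended by 50 kb 9 lay outside it, with equal list lengths 3 and with a score of 100 or more 3.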

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

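All tests in this part were chosen after the results were seen. Differences between the genotypes given here as opposite directions were not tested, because each group had 1 library.

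With IL-4 and all peaks, the IL-4 response loci had values of opposite sign relative to all genes, -0.08 in WT and 0.49 in KO. The WT value lay within the central 95% of random lists, so it showed no direction of its own. With lists of equal length, and with a score of 100 or more, both genotypes had values of the same sign. The difference with all peaks was 0.57, at percentile 97.2 of random lists and within their central 95% (-0.54 to 0.58). With loci extended by 50 kb it was 0.64, outside that range for this setting (-0.41 to 0.37). The MHC class II loci went from 9 to 7 peaks in WT and from 8 to 10 in KO, and relative to all genes stood at 0.41 and 0.69, a difference of 0.28 (percentile 66.1). By region, 207 were gained in WT and lost in KO, and 625 were lost in WT and gained in KO. With lists of equal length, which draw such counts towards balance, these were 385 and 382, and with a score of 100 or more 40 and 226.

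The shorter IL-4 lists in both genotypes could come from IL-4 libraries that detected fewer open regions of every kind. Housekeeping genes, which were not expected to close, lost their edge peak in 33.3% of cases in WT (7 of 21, interval 14.6 to 57.0) against 28.8% of all genes, and in 21.1% in KO (4 of 19, interval 6.05 to 45.6) against 22.7%. These values go with lower detection, in libraries whose depth is unknown. For the biological alternative, that IL-4 changes the same regions in both genotypes, lists of equal length had 1020 regions in exactly the 2 libraries of the same treatment, and the highest of the other 2 ways to pair the libraries had 767. With 3 ways in all, no share under 0.05 can be reached. A shared effect of IL-4 and a shared technical difference of the IL-4 libraries remain open.

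For the IL-4 response loci, the difference between KO and WT may reflect unequal list lengths, peaks near the calling threshold, or the number of list values computed. With lists of equal length it was 0.43, at percentile 91.8 of random lists, again within their central 95%. With peaks of score 100 or more it was -0.17, where the central 95% of random lists reached 1.26 to either side, so few peaks were left to decide. As 1 of many list values computed, it was also not set apart: of the 23 lists' differences between KO and WT, 0 lay outside the central 95% of random lists. An effect of the genotype on IL-4-responsive chromatin remains open and was not tested.

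At Arg1, a peak of score 121 in WT IL-4 had no counterpart in KO IL-4, which may be a peak missed at the calling threshold. Among 1074 WT IL-4 peaks with a score within 10% of it, 71 lacked a KO IL-4 peak, 6.61% (5.20 to 8.27). A single region with 1 library per group cannot be told apart from that background. A loss of accessibility at Arg1 in KO remains open and was not tested.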

How the results depend on the processing

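The alternatives requiring a score of 100 or more in one list with no peak at any score in the other were chosen after the results were seen; the other alternatives were set beforehand. Comparisons are given in the order WT IL-4 against untreated, KO IL-4 against untreated, KO against WT untreated, and KO against WT IL-4.

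On autosomes only, all 4 log2 ratios of gained over lost and all 4 shared percents stayed within their main intervals. With no peak within 500 bp the 4 log2 ratios did too, while the first 3 shared percents were 50.0, 55.6 and 61.4. With reciprocal overlap of 50% the first 3 ratios were -2.63, -1.29 and -1.25, that of KO against WT IL-4 stayed within its interval, and the shared percents were 45.3, 51.1, 55.5 and 53.1.

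With a score of 100 or more in both lists the ratios were -4.89, -2.49, -2.14 and 0.41, and the shared percents were 41.4 for WT IL-4 against untreated and 57.3 for KO against WT IL-4. Peaks then numbered 8786 in WT untreated, 3866 in WT IL-4, 6371 in KO untreated and 4179 in KO IL-4, fewer by construction. The added alternative gave -6.69, -3.07, -3.02 and 0.51. In both, each ratio kept its sign and lay further from 0; the cause was not tested.

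With lists of equal length the ratios were 0.00897, -0.013, 0.017 and -0.010, so 3 of 4 changed sign and none kept its size. Lists of equal length force the 2 counts to be nearly equal, so this alternative removes the excess of losses by construction. The first 3 shared percents were 58.7, 57.9 and 63.9. Regions gained in both genotypes numbered 454 with equal lengths and 18 with a score of 100 or more, against 127. Equal lengths left out untreated peaks with scores below 89.57 in WT and 67.78 in KO. The IL-4 lists kept peaks down to 50 in WT and 52.2 in KO. A region whose untreated peak was left out in this way counts as gained by construction. With a score of 100 or more every list is shorter. Other causes were not tested.

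Of the list values at loci, 85 of 92 moved by no more than the spread of random lists to either side with equal lengths, 87 with loci extended by 50 kb and 60 with a score of 100 or more. At that score the IL-4 response value reversed in KO, to -0.62, and was -0.11 for KO against WT IL-4. The interferon value in KO was 0.38 with equal lengths. The cause was not tested. Counts of list genes with an edge peak stayed within 1.5 times the main count in 79 of 92 cases with equal lengths and 83 with edges of 2.5 kb. The sequence motif alternatives were not run. No paired analysis was possible because each group had 1 library. Depth is unknown, so what it limits could not be computed.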

Other observations

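These values were singled out after the data were seen. The highest-scoring WT untreated peak without a counterpart in WT IL-4 or KO untreated lay on chromosome 9 at 2999940 to 3005431, with a score of 2678, 332545 bp from the nearest protein-coding gene, Alkbh8. It was the 1 region of the 30 with a score of 1000 or more that lacked a peak in some library. The next highest lost peak with IL-4 in WT scored 310, and the median WT untreated peak was 438 bp wide. No list was filtered here for repeats or regions prone to mapping errors. Whether this peak marks open chromatin was therefore not tested.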
